A study of Homo sapiens with 6 samples.

How the data were processed

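ChIPmentation libraries for ETO2 and LDB1 and input libraries were made from K562 cells, 2 of each, per the labels. Per the labels' protocols, cells were fixed in formaldehyde and sonicated, and the precipitated chromatin was tagmented on magnetic beads with a Nextera XT kit. Tagmentation inserts adapters where the transposase can reach the DNA, so peak width and height depend on that reaction as well as on binding. The libraries of each antibody share the numbers 1 and 2, and nothing in the labels says that they came from separate cultures. Differences between libraries may therefore be technical, and the p-values say nothing of other cultures.

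The deposited data used here were 6 peak lists in narrowPeak layout, 1 for each of the 4 ChIP libraries and 1 pooled list for each antibody, the latter named as pooled in the deposited lists. Bowtie2 2.3.4.1, SAMtools 1.7, Picard 2.18.0 and MACS2 2.1.1 are named in the submitters' processing notes, without their settings. Whether the input served as the control, the q threshold, any shift or extension of reads to suit Tn5 and the treatment of reads that fit several places are not given in the sources used here. In the deposited lists the fold is a linear ratio of the summit over local background, the strength of evidence is given as −log10 p (not used here) and −log10 q, and the score is the whole part of 10 times −log10 q in all but 1 peak. The lowest −log10 q in the deposited lists lay between 1.31 and 1.41. The lists give neither read counts nor signal tracks, so depth per library is unknown and peak numbers were not adjusted for it. Fold and q values are the authors' own, and they were described, ranked, filtered on or compared between classes of peaks only within a list.

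The genome build is not given in the labels. Unplaced sequences in the lists carry names that occur in GRCh38, such as those starting with KI270, and GRCh38 was used throughout with the RefSeq gene table of GRCh38.p14. Coordinates are printed counted from 1. All 242 genes of the 14 lists matched the table, which was limited to 19974 protein-coding genes. It gives neither strand nor exons. The planned transcription start sites were therefore replaced by both gene ends, the planned gene window of 10 kb upstream to the gene end by 10 kb on both sides, and the nearest gene by the gene with the nearest end.

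Peaks on chromosomes 1 to 22 and X were compared, and no list had repeated rows. Peaks overlapped when they had at least 1 bp in common. A shared peak was a pooled ETO2 peak that overlapped a pooled LDB1 peak. An ETO2-only or LDB1-only peak overlapped no peak of the other factor in its pooled or library lists and was found in both libraries of its own antibody. Overlap was tested against 1000 random rotations of the second list along each chromosome (one-sided), which keep the spacing of peaks but do not account for open chromatin or mappable sequence. Median folds were compared by 100000 permutations of the class (two-sided), shares near gene ends by Fisher's exact test (two-sided) and gene lists by 10000 random lists matched on 10 groups of gene length (two-sided), with Benjamini-Hochberg adjustment over the 14 lists. Random genes were drawn from all protein-coding genes, without matching on expression in K562, and clustered genes can share a peak. Shares have exact Clopper-Pearson 95% intervals. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

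The tests were checked on simulated data. With 60% of 12563 simulated ETO2-like peaks placed on pooled LDB1 peaks and the others off them, 60% were recovered. This checks the counting of overlaps and not the rotation test. Of 200 random gene lists of 20 with no enrichment 3% were called, and of 200 lists with 14 bound genes 100%.

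The comparisons, tests, gene lists and the rule for named items were fixed before the data were examined. Named were the 8 shared peaks with the highest −log10 q called in all 4 ChIP libraries, the 4 ETO2-only and 4 LDB1-only peaks with the highest −log10 q, up to 4 members per gene list with the highest ETO2 fold at a shared peak, and every shared peak within 100 kb of the alpha and beta globin genes. Some of the list members that this rule names are not reported here. Alternatives were 50% reciprocal overlap, summits within 100 bp, −log10 q of at least 5, all sequences, peaks in both libraries, each library number left out, library pairs of the same and of crossed number, 5 kb in place of 1 kb for gene ends, and 5 or 50 kb in place of 10 kb for gene lists. Input libraries were not analysed here, so background could not be examined directly.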

Results

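Binding of ETO2 and LDB1 was mapped in K562 cells, a human erythroleukaemia line, by ChIPmentation, a chromatin immunoprecipitation in which the Tn5 transposase adds sequencing adapters to the DNA while it is still on the beads. ETO2, encoded by CBFA2T3, is a corepressor, and LDB1 is an adaptor protein. Both join the GATA1 and TAL1 complex of erythroid cells and neither binds a DNA sequence by itself. There were 2 libraries per antibody and 2 input libraries. The input libraries had no peak list in the files used here. The ETO2 lists held 11448 peaks in library 1, 8683 in library 2 and 12677 in the pooled list. The LDB1 lists held 15452, 19437 and 26553 peaks. Median peak widths lay between 346 and 399 bp, and on chromosomes 1 to 22 and X the pooled peaks covered 5.45 Mb for ETO2 and 12.4 Mb for LDB1. The lists hold no read counts, so sequencing depth is unknown. Intervals on shares of peaks cover counting error only.

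The libraries of each antibody found largely the same places. Of the 8677 peaks of ETO2 library 2, 7882 (90.8%, exact 95% interval 90.2 to 91.4) overlapped a peak of ETO2 library 1, and 13699 of the 15447 peaks of LDB1 library 1 (88.7%, 88.2 to 89.2) overlapped one of LDB1 library 2. Rotating the other list along each chromosome gave mean overlaps of 0.32% and 0.592% (one-sided permutation test, p = 0.001 in both, the smallest that 1000 rotations can give). In the opposite direction, from the longer list to the shorter, the shares were 68.5% for ETO2 and 68.8% for LDB1. Of the pooled peaks, 7761 (61.3%) for ETO2 and 13173 (49.6%) for LDB1 overlapped a peak in both libraries. The 1594 pooled ETO2 peaks found in neither library were weak, with a median fold enrichment of 4.47 against 9.67 for those found in both. The corresponding LDB1 medians were 4.45 for 6586 peaks and 12.3.

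The first comparison asked how far the 2 factors occupied the same places. Nearly every ETO2 peak lay on an LDB1 peak. Of 12669 pooled ETO2 peaks on chromosomes 1 to 22 and X, 12455 overlapped a pooled LDB1 peak (98.3%, exact 95% interval 98.1 to 98.5). Of 26532 LDB1 peaks, 12144 overlapped an ETO2 peak (45.8%, 45.2 to 46.4), a share that the shorter ETO2 list limits by its length. Under other settings it ran from 32.9% with 50% reciprocal overlap to 64.1% between the lists of library number 1, and it was 43.2% between those of number 2. Rotated lists gave 0.826% (at most 1.18%) and 0.399% (at most 0.55%), with one-sided permutation p = 0.001 for both, the smallest possible. Between single libraries, 86.5% of the peaks of ETO2 library 1 and 98.8% of those of ETO2 library 2 overlapped a peak of the LDB1 library of the same number. With 2 libraries per antibody no exact test between libraries can go below p = 0.333, so these p-values measure position against chance and not the spread between experiments.

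The share of LDB1 peaks with an ETO2 call rose with LDB1 peak strength. When the pooled LDB1 peaks were ranked by the fold enrichment the authors' peak caller gave them, the share with an ETO2 peak was 4.18% in the lowest decile, 25.9% in the fifth, 68.4% in the seventh and 98.1% in the ninth. All 2654 LDB1 peaks of the highest decile, with folds of 21.3 to 61.1, overlapped an ETO2 peak. The ETO2 list had a much flatter course, from 91.8% of 1267 peaks in its lowest decile to 100% in each of the 3 highest. Summits at shared peaks were 40 bp apart in the median (interquartile range 15 to 78 bp), and 83.5% lay within 100 bp. In pairs of an ETO2 and an LDB1 library the medians were 40 to 48 bp, beside 41 bp between the ETO2 libraries and 49 bp between the LDB1 libraries.

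**Figure D1:**
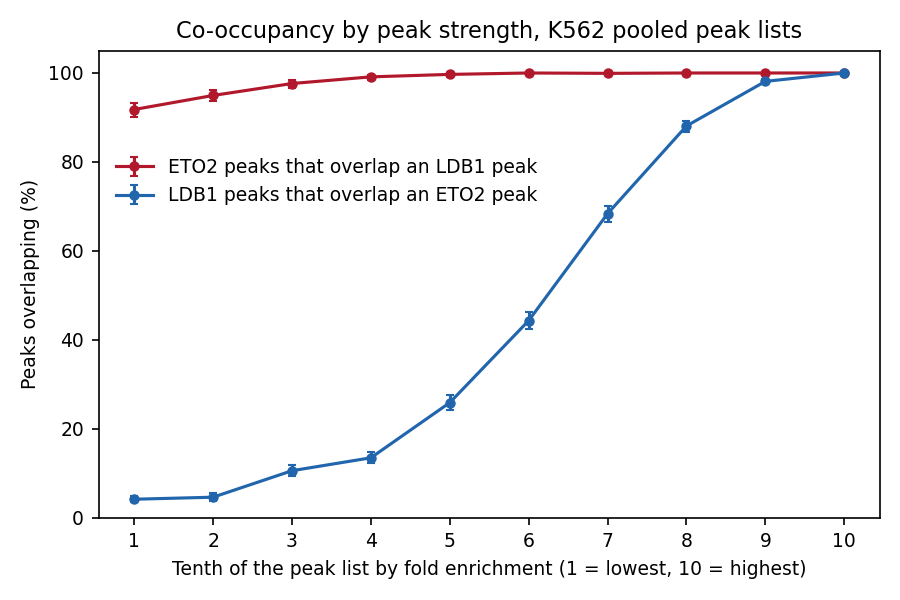
Share of pooled ETO2 peaks overlapping a pooled LDB1 peak (red) and of pooled LDB1 peaks overlapping a pooled ETO2 peak (blue), in percent, for deciles of each list by its own fold enrichment, with exact 95% binomial intervals as bars. The LDB1 line runs from 4.18% to 100% and the ETO2 line from 91.8% to 100%.

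The 8 shared peaks with the highest −log10 q in the ETO2 list lay inside 4 genes or outside genes, at up to 28.9 kb from a gene end. The highest value, 219, was at chromosome 2, 69798694 to 69799824, inside ANXA4, which encodes a calcium-dependent phospholipid-binding annexin. Its fold enrichment was 42.7 in the pooled list, with 48.6 and 63.2 in libraries 1 and 2. The next peaks were at chromosome 7, 103995613 to 103996882, 6.60 kb from an end of RELN (reelin, an extracellular matrix protein), with fold 42.2, and at chromosome 10, 61765130 to 61766266, inside CABCOCO1, with fold 41.9. Others lay 28.6 kb from NAF1, an assembly factor of small nucleolar ribonucleoproteins (fold 41.9), 15.4 kb from PPCDC, an enzyme of coenzyme A synthesis (fold 44.2), and 28.9 kb from LARP1, an RNA-binding regulator of translation (fold 39.2). A peak inside PPP3CB, a catalytic subunit of calcineurin, had a fold of 43.8. The eighth lay inside ABCB10, a mitochondrial transporter needed for heme synthesis, at chromosome 1, 229554479 to 229555847, with fold 36.8. Being called in all 4 ChIP libraries was part of the rule that picked these 8. Exons and introns were not used here.

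Peaks of ETO2 alone were rare. Of the 214 pooled ETO2 peaks without a pooled LDB1 peak, 5 were found in both ETO2 libraries and in no LDB1 list. They lay inside DPP6, an auxiliary subunit of potassium channels (chromosome 7, 154675954 to 154676305, fold 8.16), inside BCL2L1, which encodes the survival protein BCL-XL (chromosome 20, 31708330 to 31708652, fold 6.67), 40.1 kb from the laminin gene LAMA1 (chromosome 18, 7157800 to 7157996, fold 5.34) and inside the tumour antigen gene PRAME (chromosome 22, 22558029 to 22558515, fold 4.05). The fifth, inside OSBPL3 with fold 5.43, fell outside the rule for named peaks and is given because only 5 existed. Shared ETO2 peaks had a median fold of 7.11 against 5.43 for these 5, a ratio of 1.31 that did not pass the two-sided permutation test (p = 0.369). All 5 had to be in both ETO2 libraries, as 62.3% of the shared peaks were. With both lists limited to peaks in both libraries, which leaves 17 ETO2-only peaks and was fixed before the data were examined, the medians were 9.83 and 5.53 and the ratio of 1.78 passed (permutation p = 5e-04), as did ratios of 1.61 and 1.56 without library numbers 1 and 2 (p = 5e-04 in both), but 1.46 at −log10 q of at least 5 did not (permutation p = 0.056). Against all 214 peaks without LDB1, a set chosen after the data were seen, the ratio was 1.62 (permutation p = 5e-04). That is the smallest p that 2000 permutations can give.

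LDB1 peaks with no ETO2 call were more numerous, though weaker. By the same rule 2449 pooled LDB1 peaks were LDB1-only, and a further 11939 had no pooled ETO2 peak but were missing from at least 1 LDB1 library or overlapped a peak of an ETO2 library. Shared LDB1 peaks had a median fold of 13.1 and LDB1-only peaks 7.79, a ratio of 1.68 (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). The LDB1-only peaks with the highest −log10 q were 54.0 kb from GZMB, which encodes granzyme B (chromosome 14, 24687775 to 24688406, fold 21.3), inside ZNF688, a zinc finger gene (fold 20.1), inside THRAP3, a factor of RNA splicing (chromosome 1, 36275602 to 36276114, fold 19.2), and 8.45 kb from FGF13 (chromosome X, 139213190 to 139213923, fold 17.8). At the GZMB peak the libraries gave folds of 8.44 and 21.3. Peaks are not replicates, so this p-value describes the peaks of these lists.

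Most peaks of either class lay away from gene ends. Within 1 kb of either end of a protein-coding gene lay 588 of 12455 shared summits (4.72%, exact 95% interval 4.36 to 5.11) and 151 of 2449 LDB1-only summits (6.17%, 5.25 to 7.19). Both were above the rotated means of 2.61% and 2.54%. The classes differed (odds ratio 0.754, two-sided Fisher's exact test, p = 0.00365), but within 5 kb they did not pass the test, at 19.5% and 20.4% (p = 0.33). The difference of -1.44 percentage points was -1.72 with peaks in both libraries (Fisher's exact test, p = 0.000224). At −log10 q of at least 5 it was -1.54 (Fisher's exact test, p = 0.00107). With the lists of library number 2 alone it was -0.644 (Fisher's exact test, p = 0.0414). There LDB1-only meant a wider class, all 11030 peaks of LDB1 library 2 without a peak in ETO2 library 2. None of the 5 ETO2-only summits lay within 1 kb. Inside protein-coding genes lay 54.5% of shared and 57.5% of LDB1-only summits, against 43.0% and 42.7% after rotation. Gene strand was not used here, so a gene's start and its far end were not told apart.

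The globin loci carried strong peaks of both factors outside the genes. In the beta-globin region, taken with 100 kb on either side of the outermost genes, all 14 ETO2 peaks overlapped an LDB1 peak, and 14 of 22 LDB1 peaks overlapped an ETO2 peak. The highest ETO2 folds were beyond HBE1, the embryonic epsilon-globin gene, on the side away from HBB, where the locus control region, the distal enhancer cluster of the locus, is known to lie. There, ETO2 peaks stood at chromosome 11, 5280369 to 5281077, with fold 24.1 (25.5 and 20.0 in libraries 1 and 2), 5284329 to 5285289 with fold 26.2 (23.6 and 25.04), and 5288081 to 5288504 with fold 13.4 (9.35 and 11.9). Weaker peaks on the same side were at 5275780 to 5276156 with fold 8.24 and 5297702 to 5297992 with fold 6.91. Within HBB, the adult beta-globin gene, a shared peak at 5225554 to 5225898 had a fold of 5.43, and 1 at 5224640 to 5224806, 0.749 kb beyond the gene, had 4.94 and was found in ETO2 library 1 only. HBG1 and HBG2, the fetal globin genes, had no pooled ETO2 peak within 10 kb. The LDB1 peaks nearest to them, with pooled folds of 6.15 and 3.69, were unshared, though ETO2 library 1 alone had a peak of fold 4.59 at the former. Among the olfactory receptor genes that flank the locus, shared ETO2 peaks lay at 5131674 to 5132405 inside OR52A5 (fold 15.8), 5151491 to 5152373 inside OR52A1 (fold 12.3), 5160121 to 5160762 (fold 11.02), 5164824 to 5165224 (fold 10.1) and, on the other side, 5335177 to 5335551 (fold 10.7). The last 2 of the 14, at 5129421 to 5129679 and 5171945 to 5172169, had folds of 5.06 and 3.95.

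In the alpha-globin region all 6 ETO2 peaks overlapped LDB1 peaks, and 6 of 12 LDB1 peaks overlapped ETO2 peaks. The strongest ETO2 peak, at chromosome 16, 112972 to 114113, lay inside NPRL3, the neighbouring gene known to house the major alpha-globin enhancers, with a fold of 22.5 (29.2 and 27.1 in libraries 1 and 2). Also inside NPRL3 were peaks at 104913 to 105352 (fold 10.4) and 119772 to 120445 (fold 11.2). Between NPRL3 and HBZ, the embryonic zeta-globin gene, stood peaks at 142939 to 143514 (fold 15.3) and 144784 to 145259 (fold 10.1). The sixth, inside FAM234A at 259359 to 259536, had a fold of 4.15 and was in neither ETO2 library. HBA1 and HBA2, the near-identical alpha-globin genes, had no pooled ETO2 peak within 10 kb. Calls at such copies, as at HBG1 and HBG2, depend on how reads that fit several places were treated, which is not given in the sources used here.

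**Figure D2:**
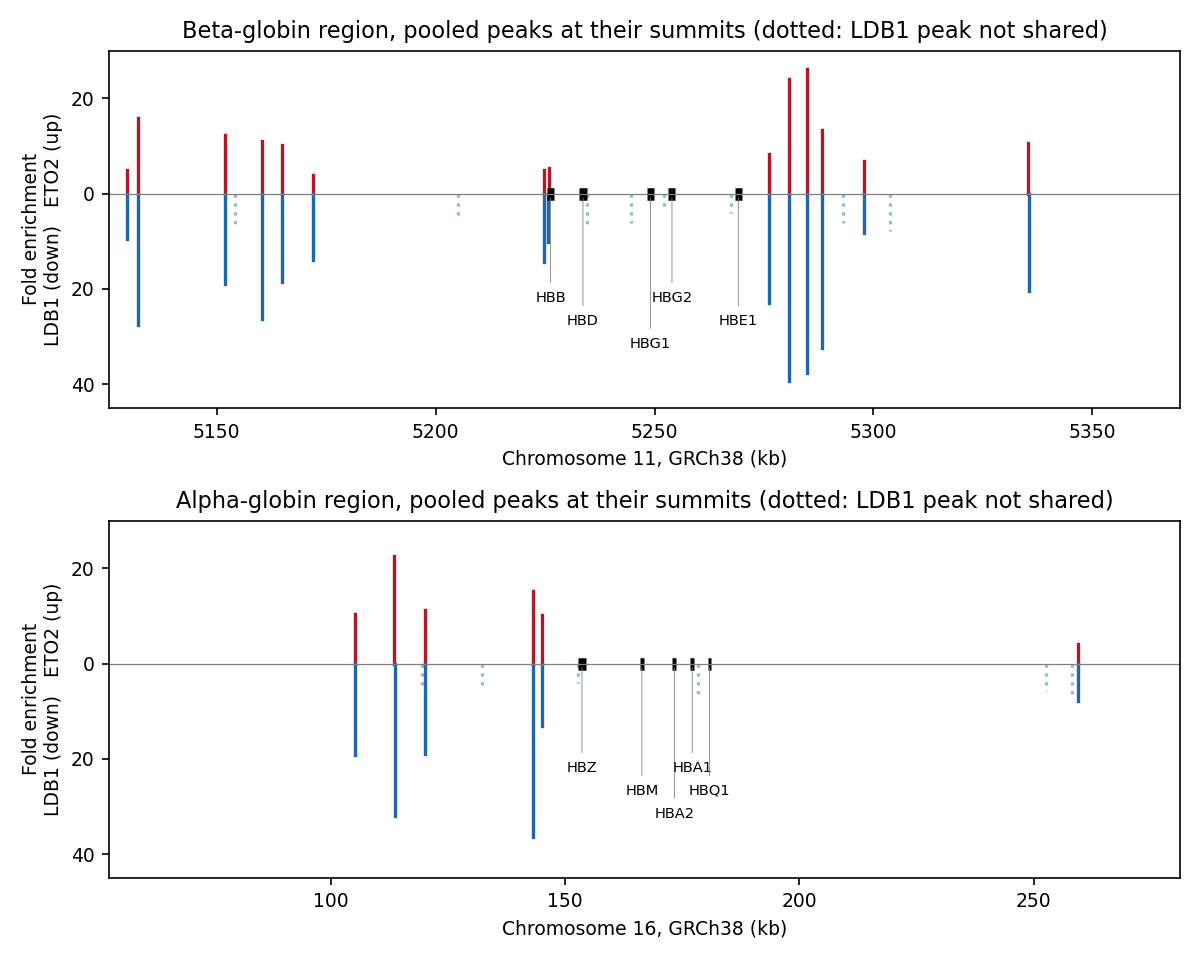
Fold enrichment of pooled ETO2 peaks (red, upward) and pooled LDB1 peaks (blue, downward, solid where shared with ETO2 and dotted where not) at their summits, along the beta-globin region on chromosome 11 and the alpha-globin region on chromosome 16 (x axes in kb, black bars are globin genes). The highest ETO2 lines are at 26.2 beyond HBE1 and 22.5 inside NPRL3, and each has an LDB1 line under it.

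Genes of red cell function carried shared peaks far more often than random genes. A gene was counted when a shared peak's summit lay inside it or within 10 kb of either end, which held for 5526 of 19974 protein-coding genes (27.7%). Of 14 gene lists fixed before the data were examined, 5 exceeded 10000 random lists matched on gene length, each with a Benjamini-Hochberg adjusted p of 0.00056 (two-sided permutation test over matched lists, the smallest value possible here). In the red cell membrane and blood group list 21 of 22 members had a shared peak, against 7.05 in random lists. The strongest, fold 37.9 in the ETO2 list, was at chromosome 1, 28883408 to 28885407, near EPB41, the cytoskeletal protein 4.1. SLC2A1, the glucose transporter of red cells, had a fold of 36.2, ERMAP, which carries the Scianna blood group, 32.7, and SLC4A1, the band 3 anion exchanger, 28.6. ACKR1, which carries the Duffy antigens, was the member without a shared peak.

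In the heme and iron list 16 of 18 members had a shared peak, against 4.43 in random lists. Besides ABCB10, the strongest were in ALAS2, the erythroid enzyme of the initial step of heme synthesis (chromosome X, 55014789 to 55015678, fold 31.6), CPOX, coproporphyrinogen oxidase (fold 30.1), and 1.12 kb from SLC25A37, the mitochondrial iron importer mitoferrin (fold 26.4). FTL and STEAP3 had none. Among 21 genes for the LDB1 complex and corepressors 16 had a shared peak, against 7.11. GATA1, the master erythroid transcription factor, had 5 shared peaks, the strongest at chromosome X, 48800293 to 48801276, 6.38 kb from the gene, with fold 30.1. RUNX1T1, which encodes the ETO protein related to ETO2, had a fold of 17.3, and TAL1 and LDB1 both 17.0. The ETO2 gene itself, CBFA2T3, which falls outside the rule for named genes and was chosen after its values were seen, had 2 shared peaks, the stronger at fold 11.02.

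Of 24 other erythroid regulators 18 had a shared peak, against 9.02 in random lists. Among the high folds were 36.6 in RUNX1 (chromosome 21, 34908148 to 34909162), a factor of blood cell development, 32.2 in NFE2, which activates globin genes, and 30.4 in ZFPM1, the GATA1 partner FOG1. Of 16 genes of cytokine signalling in erythroid cells 13 had a shared peak, against 5.12. LYN, a tyrosine kinase, had a fold of 24.1 (chromosome 8, 56013763 to 56014367), BCL2L1 20.2, the phosphatase gene PTPN6 16.1 and the kinase gene PIM1 13.5.

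The other blood lineages and the globin list did not pass after adjustment. Shared peaks were near 4 of 10 globin genes (random mean 1.09, adjusted p = 0.0584 in the same permutation test), with ETO2 folds of 15.3 for HBZ, 8.24 for HBE1 and 5.43 for HBD and HBB, which were assigned the same peak. They were near 9 of 20 megakaryocyte genes (random mean 4.43, adjusted p = 0.0584 by permutation), led by the platelet glycoprotein gene GP9 at 20.7, PLEK at 12.8, the integrin gene ITGA2B at 12.5 and the thrombin receptor gene F2R at 12.2. They were near 7 of 15 myeloid genes (random mean 3.01, adjusted p = 0.0584 by permutation), led by CEBPE at 15.5, CSF1R at 10.7, CSF3R at 8.58 and the lysozyme gene LYZ at 8.04. These 3 lists passed under some settings and not others. Globin genes with a shared peak were 10 of 10 within 50 kb (permutation adjusted p = 0.0014) but 1 of 10 within 5 kb (0.977), myeloid genes 13 of 15 (0.0084) and 4 of 15 (0.468), and megakaryocyte genes 13 of 20 (0.215) and 9 of 20 (0.0121). The globin genes lie in an alpha and a beta cluster, whose members can be counted through the same peak. Random genes were drawn singly, so low p-values of the globin list overstate the evidence. With either library number left out, the globin and megakaryocyte lists passed and the myeloid list did not.

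Lists for other tissues and for housekeeping genes did not pass within 10 kb. Counts were 2 of 15 T cell genes (CD2 at fold 10.7 and ZAP70 at 9.89; permutation adjusted p = 0.65), 2 of 12 B cell genes (among them FCER2 at 3.08; 0.707) and 3 of 16 neuron genes (GAD2 at 14.3, GAD1 at 7.44 and SYT1 at 2.96; 0.339). A single hepatocyte gene of 16 had a shared peak (TF, the transferrin gene, at fold 19.1; permutation adjusted p = 0.198). The remaining counts were 4 of 22 ribosomal protein genes (RPS3 at 17.0, RPS9 at 9.83, RPL15 at 4.26 and RPS4X at 3.95; 0.882) and 6 of 15 cell cycle genes (0.296). Among the latter were the D-type cyclin gene CCND3 at fold 29.4, E2F1 at 16.1, CCNE1 at 8.93 and MYC at 7.89. Within 50 kb, a distance also fixed before the data were examined, the ribosomal protein list (16 of 22, random mean 9.83, permutation adjusted p = 0.0297) and the cell cycle list (12 of 15, random mean 7.18, 0.0348) passed, and the T cell, B cell, neuron and hepatocyte lists did not.

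**Figure D3:**
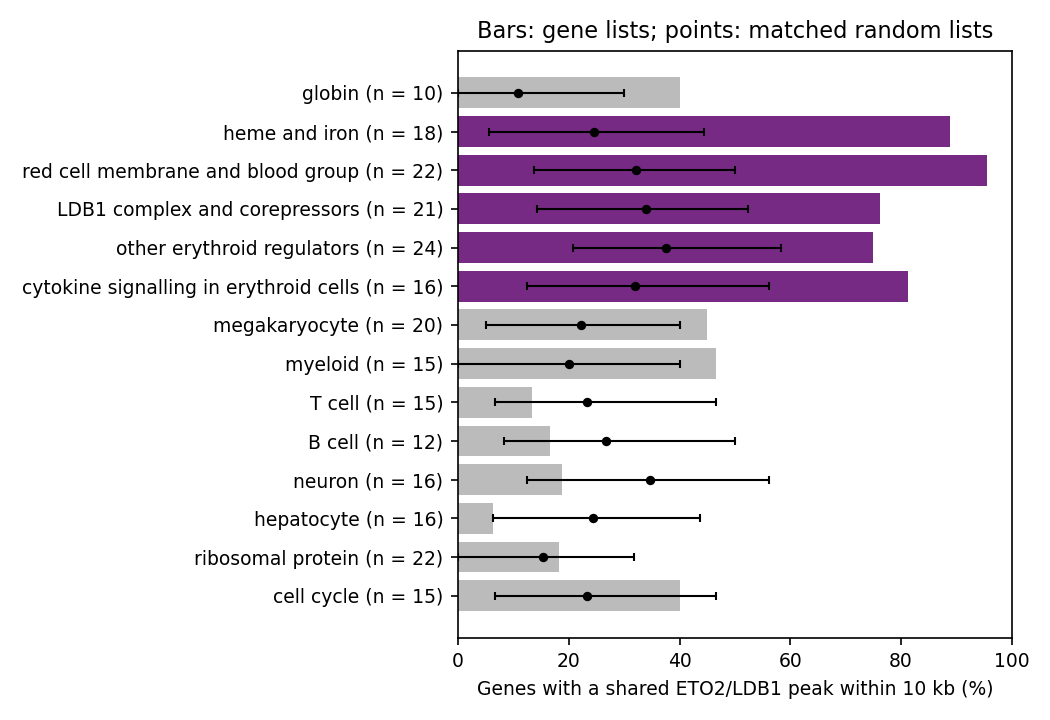
Percent of genes in each of 14 lists with a shared ETO2 and LDB1 peak inside the gene or within 10 kb (bars, purple where the adjusted p was under 0.05), beside the mean and central 95% range of 10000 random lists matched on gene length (points with bars). The red cell membrane and blood group list stands at 95.5% against a random mean of 32.1%, and the hepatocyte list at 6.25% against 24.3%.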

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

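The tests of the chromosome 13 pattern were chosen after the result was seen. Signals in parts of the lists outside the comparisons led to the following. Outside chromosomes 1 to 22 and X, on unplaced sequences, lay 8 pooled ETO2 peaks and 21 pooled LDB1 peaks. Of the ETO2 peaks there 6 overlapped an LDB1 peak, and the highest fold was 9.23.

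ETO2 library 1 held 882 peaks that overlapped no peak of the pooled ETO2 list, against 82 in ETO2 library 2, 470 in LDB1 library 1 and 88 in LDB1 library 2. Of the 882, 115 (13.0%) lay in 5 bins of 1 Mb on chromosome 13, at 80 to 81 Mb and 89 to 93 Mb. These bins were found by searching for bins with at least 10 peaks in a library and at most 10% as many in its repeat, and no other bin met that rule for either antibody. They held 125 peaks of ETO2 library 1, 2 of ETO2 library 2, 12 of LDB1 library 1 and 8 of LDB1 library 2.

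The tables argue against ETO2 binding of the usual kind in these bins, since 6.4% of the 125 peaks overlapped a pooled LDB1 peak (exact 95% interval 2.80 to 12.2) against 97.1% elsewhere in the library. Among peaks with no counterpart in ETO2 library 2, the kind that the search favours, the shares were 4.88% of 123 in the bins and 90.9% of 3486 elsewhere. The search that found the bins fixed a high peak density there in ETO2 library 1 and a low one in ETO2 library 2. Only the LDB1 libraries are free of that rule. Peak density in the bins over the rest of the chromosome was 15.2 in ETO2 library 1 (95% interval 12.0 to 19.2). It was 1.06 in LDB1 library 1 (0.539 to 1.88) and 0.525 in LDB1 library 2 (0.225 to 1.05). These LDB1 values argue against extra copies of the segment that raise calls alike in every library. Extra copies that raise calls in ETO2 library 1 alone were not tested, as peak lists do not measure copy number. A raised background in this library stays open, since the median fold of the 117 peaks in the bins with neither a repeat nor an LDB1 peak, 4.39, lay within the interquartile range of such peaks elsewhere (4.25 to 5.04) and so decides nothing. Input and read coverage were not analysed here, and no biological explanation was tested.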

How the results depend on the processing

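Both overlaps between the factors and both replicate overlaps exceeded rotated lists under every alternative run. ETO2 peaks on LDB1 peaks ranged from 68.8% with 50% reciprocal overlap to 98.8%, and LDB1 peaks on ETO2 peaks from 32.9% to 64.1%. Library numbers are shared between the antibodies but nothing says that they pair the samples. As a replicate block, same-numbered pairs averaged 92.6% and 53.6%, against 93.3% and 52.9% for crossed pairs, and no call changed. Shared against LDB1-only folds kept their call throughout.

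The ratio of shared to ETO2-only folds, 1.31 and not called, was 1.78 with peaks in both libraries, 1.56 to 1.61 when a library number was left out, and 1.62 with all 214 ETO2 peaks without LDB1, a set added after seeing the data, and passed the test in each. At −log10 q of at least 5 it was 1.46 and did not pass (permutation p = 0.056). The left-out, both-library and −log10 q settings define ETO2-only against fewer LDB1 peaks, so their class takes in ETO2 peaks on a pooled LDB1 peak. With a number left out, ETO2-only and LDB1-only peaks were all peaks of 1 library without one in the other factor's library of the same number. The gene end difference of -1.44 percentage points was -0.857 at 5 kb and no longer passed. It was -1.72 with peaks in both libraries and -1.54 at −log10 q of at least 5. With the wider LDB1-only class of the left-out settings it was -0.644 without number 1 and -1.23 without number 2. Median summit distance was 33 bp with peaks in both libraries and 40 to 48 bp with a number left out. The number of gene lists called, 5, was 9 within 50 kb, 8 with any LDB1 peak and 5 without genes named LOC (both added after seeing the data), 7 at −log10 q of at least 5, 7 with either number left out and 6 within 5 kb. The globin list passed at −log10 q of at least 5 (adjusted p = 0.0424 by permutation) and without number 1 or 2 (0.0188 and 0.0308), and so did the megakaryocyte list (0.0369, 0.0098 and 0.0187). With any LDB1 peak the globin, megakaryocyte and myeloid lists passed (0.000933, 0.0318 and 0.000933). The window decided the rest: globin genes with a shared peak were 10 of 10 within 50 kb (0.0014) and 1 of 10 within 5 kb (0.977), myeloid genes 13 of 15 (0.0084) and 4 of 15 (0.468), and megakaryocyte genes 13 of 20 (0.215) and 9 of 20 (0.0121). Clustered globin genes can share a peak but were counted singly, so low p-values of that list overstate the evidence. At 50 kb the ribosomal protein and cell cycle lists passed too, at adjusted p of 0.0297 and 0.0348.

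Members above or below the random mean changed sign without passing the test in 3 lists: ribosomal protein genes from 0.625 members above it to -1.001 at −log10 q of at least 5 and -0.725 to -0.448 with a number left out, B cell genes from -1.20 to 0.0544 at 50 kb, and T cell genes from -1.50 to 1.04 with any LDB1 peak. The cause was not tested for any of these. The planned count of GATA motifs was not run, as no genome sequence was used here. Unknown depth limits every statement that a peak is missing.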

Other observations

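All tests in this part were chosen after the results were seen. Shared peaks were crowded at some loci. Among 2057 bins of 1 Mb with at least 1 shared peak, the median was 5 shared peaks. The bin at 15 to 16 Mb of chromosome 6, which holds JARID2, a subunit of the Polycomb repressive complex, had 37. There were 30 at 207 to 208 Mb of chromosome 1. That bin holds, among other genes, the complement receptor genes CR1 and CR2, the complement regulator gene CD55 and the stem cell marker gene CD34. CR2 had no shared peak within 10 kb. Counts are for whole bins and not for the genes named. Bins with MTSS1 on chromosome 8 and MICAL2 on chromosome 11 had 29 and 28, and the bin of the beta-globin and olfactory receptor genes 25. Counting the gene and 10 kb on either side, ZFPM2, which encodes the GATA partner FOG2, had 18 shared peaks over 486 kb. GSE1 had 17, SND1 16, and DLGAP1 and SGMS1 14 each. The erythroid regulator SOX6, lower in this ranking and level with several other genes, had 11 over 772 kb. Among genes with at least 5 shared peaks, PPP1R15A, a stress response gene, had the most for its length, with 5 shared peaks in and around 3.64 kb, followed by BTG2, an antiproliferative gene, with 5 around 4.08 kb, and GATA1.

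LDB1-only peaks exceeded random lists in 2 of the 14 gene lists. They lay in or within 10 kb of 13 of the 24 other erythroid regulators, against 3.27 in random lists (permutation adjusted p = 0.0028, over 14 lists), and of 7 of the 16 cytokine signalling genes, against 1.71 (permutation adjusted p = 0.0084). KLF13 and E2F4 of the regulators and the cytokine receptor gene KIT had an LDB1-only peak and no shared peak. The others of these 13 and 7 genes also had a shared peak. Any LDB1 peak was near 21 of the 24 regulators and 16 of the 16 cytokine signalling genes. Random lists were not matched on that, so the excess is not shown to be particular to LDB1-only peaks. The LDB1 complex and corepressor list had 6 of 21 members with an LDB1-only peak, against 2.56 (permutation adjusted p = 0.268). The heme and iron list had 3 of 18 members with an LDB1-only peak (permutation adjusted p = 0.529) and the globin list 0 of 10 (random mean 0.259, permutation adjusted p = 1).

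The LDB1 peaks without an ETO2 call are open to a pair of readings. ETO2 peaks missed below the detection limit may account for part of them. In the highest LDB1 decile 100% had an ETO2 peak, and the share fell steadily with LDB1 fold. That gradient cannot tell missed ETO2 peaks from absent ETO2. Of the 2449 LDB1-only peaks, 1572 lay above the median fold of the pooled LDB1 list. The eighth decile held 264 of them and the ninth 44. These counts follow in part from the class rule, which asks for a peak in both LDB1 libraries. That held for 1.24% of LDB1 peaks in the lowest decile and 100% in the highest. All 14388 LDB1 peaks without a pooled ETO2 peak had a median fold of 5.07, below the 6.97 of the whole list. LDB1 sites placed differently from the shared ones were tested within deciles of LDB1 fold. The pooled odds ratio of lying within 1 kb of a gene end was 1.27 for LDB1-only over shared (95% interval 1.03 to 1.55, Mantel-Haenszel chi-square test over peaks, p = 0.0221), but 1.01 within 5 kb (0.898 to 1.14, p = 0.872), and the demand that both distances pass was set after the 1 kb value was known. Whether such sites exist stays open, because the 2 distances give different answers and ETO2 reads at these sites were not analysed here.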
